A study of Mus musculus with 16 samples.

How the data were processed

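RNA, histone marks and DNA methylation were measured in β cells sorted by flow cytometry, per the labels' protocols. The protocol for RNA names mice carrying a green fluorescent protein driven by the insulin promoter, and the strain label is MIP-GFP/Bl6 for RNA and C57Bl6 for chromatin and bisulfite samples. Whether the latter mice carried the reporter was left open. Young animals were 4 to 6 weeks old. The 3 old RNA pools were labelled 15, 16 and 17 months, and the old chromatin and bisulfite pools 16 to 18 months. The design text gives pools of 5 to 10 mice for an RNA library, a pool of 10 young mice for bisulfite sequencing, and another age range for the old bisulfite pool than its label, so the exact age of that pool was left open. RNA was held for 3 old and 2 young libraries. Each histone mark and each bisulfite sample was held as 1 sample per age, though the design text names 2 old H3K27me3 replicas, and whether the old list joins them was left open. H3K27ac, a mark of active regulatory elements, was held for young cells only. The 4 input libraries of the chromatin experiments carried no files of their own and were not analysed here.

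The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.7, STAR, HOMER and edgeR for the series, without saying which step each served, and the genome build mm9, which all coordinates here use. The deposited RNA table holds whole-number read counts per RefSeq transcript, with 28644 transcripts of 22869 genes, and no entry without a gene name. Transcripts of the same gene held nearly equal counts in that deposited table, so reads shared by transcripts were counted for each of them. Whether reads were counted by strand is not given in the sources used here, so antisense partners such as Tsix and Xist, overlapping genes and near-identical copies such as Ins1 and Ins2 may share reads. A second deposited table, described as FPKM, was treated as a signal of unknown scale. In it the columns of the third old library and of the shallower young library were identical in 100% of entries, so it was used only for transcript positions, and 22534 genes had 1 position. Per the file headers, H3K4me1 and H3K27ac peaks were called with HOMER findPeaks on 1 library against 1 input library, at a false discovery rate of 0.01, at least 2-fold over input and a p-value over input of 0.0001. H3K4me1 peaks had a fixed width in each list, and H3K27ac peaks were stitched regions. The deposited HOMER score of each peak was used only to rank peaks within a list. The H3K27me3 lists have no header, their caller is not given in the sources used here, and their deposited score and p-value columns are unlabelled, so the score served only to rank regions within a list. The deposited CpG tables hold for each CpG the methylated fraction and the read coverage, with both strands merged. Methylated calls were recovered as fraction times coverage, and the products lay within 1.9e-08 of a whole number. The name of these tables points to BS-Seeker, and its filters and any correction for incomplete conversion are not given in the sources used here.

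For RNA, the transcript with the highest total count stood for each gene. The 3 old and 2 young libraries were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM factors and the filterByExpr filter, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All fold changes are old over young. The young columns carry no replicate number, so these libraries are called the shallower and the deeper young library here. Their column names end in 10K and 102K, which may stand for numbers of cells, and a difference in input between the young libraries stays open. Levels are counts scaled to the library size (CPM), and log2 fold changes carry the standard error (SE) of the model. Where a group had no count, the fold is a bound against 3 counts over that group. Of 24 gene lists, each was tested with camera (limma 3.58.1, preset correlation 0.01) and, as checks, with camera at an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its members move one way on balance. Each list was adjusted over the 24 lists. The lists, the tests, the thresholds, most alternatives and the rule for the genes and peaks named were fixed before the data were examined. The rule took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM, with no overlap between the groups and without a clone name, up to 4 called members of each list with the smallest adjusted p, and 21 genes of β-cell function, proliferation, methylation and neighbouring islet cells in any case. For peaks it took the 5 largest losses and gains of each H3K4me1 list with at least 5 CpGs, and up to 2 called peaks within 50 kb of the start of a named gene. Whether a called gene has unusual GC content or length was not tested, since no genome was at hand, and exon or intron positions of peaks are not given for the same reason. Positions inside the span of a transcript are given where the tables allow. Of the genes that this rule takes, 1 is not reported here.

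For methylation, CpGs with at least 5 calls in both libraries were used. A region needed at least 3 such CpGs and 20 calls in each library. Its methylated and unmethylated calls were compared with Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg within each set of regions, and called at an adjusted p under 0.05 with a difference of at least 20 percentage points. Sets were the 5 peak lists, 1 kb windows over the genome, and promoters from 1000 bp before to 500 bp after the gene start. With 1 library per age these tests compare 2 libraries and not the ages, and calls from the same read are not independent. Intervals are exact binomial intervals at 95% and cover counting error only. Peaks overlapping by at least 1 bp were counted as shared. For expression, the gene was tied to its nearest peak more than 2 kb and at most 50 kb from its start, and H3K27me3 was scored within 1 kb of the start. Medians were compared by two-sided permutation tests across genes or regions with 100000 permutations, or 2000 where an RNA library was left out or peak classes were rebuilt, and genes and regions are not independent replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 served these steps, and matplotlib 3.10.9 the figures.

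RNA depth was 23559908 to 33562822 gene counts in the old libraries, 6377619 in the shallower and 12892123 in the deeper young library. No 2 libraries of a group were copies of each other: their counts differed by 49.0 to 109.8 times sampling noise (chi-square per degree of freedom), and the labels do not say more of the pools' independence than that they are biological replicates. With counts simulated at the observed means, depths and spread over 15103 genes, the RNA comparison recovered 2% of 50 genes changed 2-fold, 32% of 50 changed 4-fold, 72% of 50 changed 16-fold and 80% of 50 changed 64-fold, with 5 false calls. A change of small size was therefore mostly out of reach. The bisulfite tables held 812407715 young and 572520813 old calls, with a median of 16 young and 18 old calls per CpG. In calls simulated over 43470 windows of chromosome 19, 66% of 100 windows with a true difference of 30 points met the calling rule. With a true difference of 10 points 0 of 100 met it, and there was 1 false call. The rule requires at least 20 points, so the outcome at 10 points followed from the rule and does not measure power. Whether these figures hold for peaks and promoters, at other methylation levels or for calls sharing a read was not tested.

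Alternatives for the RNA comparison were RLE factors, no filter, a filter at 5 CPM, DESeq2 1.42.0, a fold limit and leaving out each library. For methylation they were other call minimums, other differences, centring, autosomes only, leaving out the deepest CpGs, higher-scoring peaks and thinned CpGs, and for overlaps a longer overlap, higher-scoring peaks and lists of equal length. Those chosen after the data had been seen were counts summed over transcripts, all transcripts, library sizes without Ins1 and Ins2, old libraries thinned to the depth of the shallowest library, wider H3K4me1 peaks, leaving the deepest CpGs out of the genome-wide level, and leaving out each RNA library from the comparisons of expression with peaks and promoters.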

Results

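The series set pancreatic β cells of old mice beside those of young mice and asked how transcripts, histone marks at regulatory elements and cytosine methylation differ with age, in cells that become better at releasing insulin according to the title of the study. RNA was sequenced from 3 pools of old and 2 pools of young sorted β cells. H3K4me1, found at enhancers, and H3K27me3, the mark set by Polycomb repressive complex 2, were mapped in 1 library per age, H3K27ac in 1 young library, and CpG methylation in 1 library per age. Old RNA libraries held 23559908 to 33562822 gene counts, the shallower young library 6377619 and the deeper young library 12892123. Ins1 made up 22 to 28.3% of all counts in each of the 5 libraries. Old libraries correlated with each other across genes at 0.979 to 0.983 (Pearson's r of log2 CPM). The young libraries correlated at 0.833, so the spread within the young group was the wider one. Over tested genes scaled with TMM factors, the young libraries correlated at 0.71 with each other. By that measure the deeper young library correlated more closely with the old libraries (0.722 to 0.742), and the shallower one less closely (0.674 to 0.679).

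In old β cells, gene lists of proliferation and of other pancreatic cell types were lower, and lists of β-cell function, the unfolded protein response and respiration were higher, by camera at its preset correlation. With an estimated correlation none of the 24 lists passed. Of 15544 genes tested, 492 rose and 1232 fell (edgeR, adjusted p under the threshold of 0.05). Mki67, a marker of dividing cells on chromosome 7 (142881471 to 142908062), fell from 328 ± 29.5 CPM (SD, n = 2) to 1.75 ± 0.45 CPM (SD, n = 3), a log2 change of -7.55 (SE 0.33, adjusted p = 0.000189). Slc2a2, the glucose transporter of β cells on chromosome 3 (28596825 to 28627282), rose from 227 ± 40.6 to 474 ± 63.0 CPM, a log2 change of 1.07 (SE 0.24, adjusted p = 0.0315). Leaving out old library 1, 2 or 3 left 331, 441 or 368 called genes, of which 40, 50 and 95 rose. Leaving out the shallower or the deeper young library gave 3243 or 5467, of which 1296 and 2368 rose, with the remaining young library assumed to vary like the old ones, and DESeq2 called 4154, of which 1185 rose. RLE factors moved the median of all genes from -0.05 to -0.174 on the log2 scale, and all fold changes are to be read relative to that.

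Among the largest rises, Fut1, a fucosyltransferase gene, was at least 74.3-fold higher in old cells and the olfactory receptor gene Olfr330 at least 56.9-fold, since neither had a count in the young libraries. Gabra4, a subunit of the GABA-A receptor, rose from 0.364 ± 0.304 to 24.2 ± 1.03 CPM, a log2 change of 5.89 (SE 0.73, adjusted p = 0.00554). Rph3a, which encodes the vesicle protein rabphilin, rose by 5.11 (SE 0.84, adjusted p = 0.0134). The other 6 genes of this group, Lcmt2, Slc4a10, Gbp11, Tpd52l1, Ghdc and Slc25a35, had log2 changes of 4.06 to 4.3. Each of the 10 largest falls had no count in any old library. Clca3 was at least 526-fold lower, Lgals2 at least 488-fold, Olfr373 at least 473-fold, Palm3 at least 416-fold, Dio2, the activating thyroid hormone deiodinase, at least 415-fold, and Cmah at least 390-fold. The bounds for Tmem45a, Skint1, Muc13 and Zfp804a lay between 273-fold and 328-fold. Apart from those of Lgals2 and Cmah, these bounds rested mostly on the shallower young library: Palm3 lay there at 39.7 CPM and in the deeper one at 1.45 CPM, Olfr373 at 42.8 and 2.75 CPM, Clca3 at 40.1 and 6.73 CPM, and Zfp804a at 26.1 and 0.869 CPM. Of the 99 called genes that the naming rule takes, 55, 51 and 51 were no longer called without old library 1, 2 or 3.

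**Figure D1:**
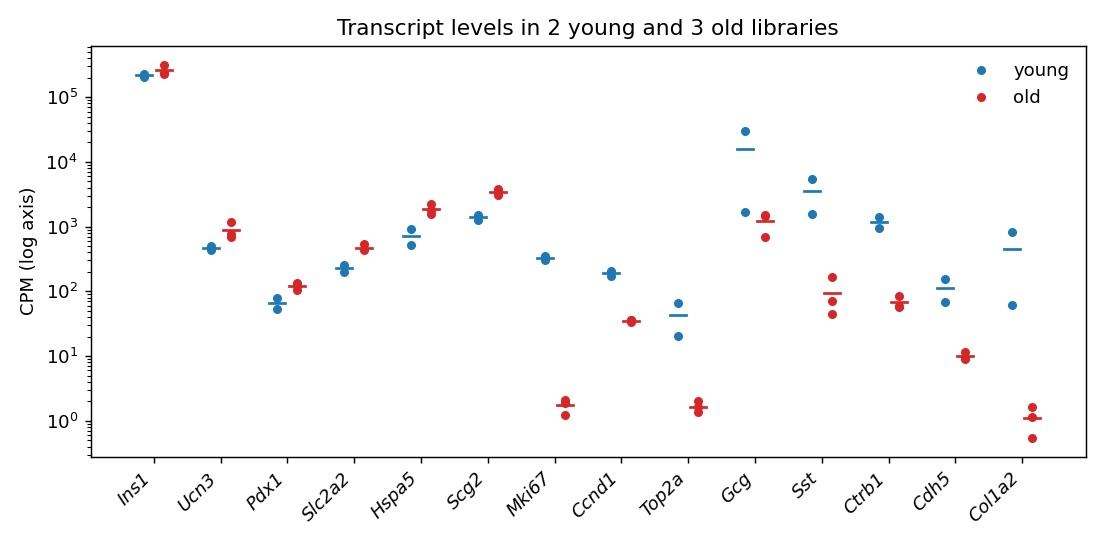
Transcript levels (CPM, log axis) of 14 genes in each of 2 young (blue) and 3 old (red) libraries, with horizontal bars at the group means. Mki67 lay at 1.75 CPM on average in old and 328 CPM in young libraries, while the insulin gene Ins1 lay near the top of the axis in all 5 libraries.

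Among genes of β-cell function more rose than fell in old cells: of 43 tested members, 10 rose, 1 fell and 32 did not pass the test, and 15 rose and 1 fell when adjusted over the list alone. The median log2 change of the list was 0.61 (camera adjusted p = 2.88e-06, and adjusted p = 0.0882 with an estimated correlation). Scg2, a granin of dense-core secretory granules, rose from 1398 ± 190 to 3460 ± 327 CPM, a log2 change of 1.31 (SE 0.23, adjusted p = 0.0163). Scg5, a chaperone of the prohormone convertase PC2, rose by 1.38, Trpm5, a calcium-activated cation channel, by 1.37, and Gjd2, the gap junction protein that couples β cells, by 1.79. The insulin genes did not pass the test, with log2 changes of 0.27 for Ins1 (SE 0.28, adjusted p = 0.561) and 0.50 for Ins2 (SE 0.32, adjusted p = 0.339). Ucn3, a marker of mature β cells, had a log2 change of 0.93 (SE 0.29, adjusted p = 0.0723), and Glp1r, the incretin receptor, one of 0.84 (SE 0.37, adjusted p = 0.176). Without old library 1 or 2 no member of the list was called, and without old library 3 only 3 were.

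Transcription factors of β cells showed no common direction. Of 34 tested, 1 rose, 2 fell and 31 did not pass the test, with 4 and 6 adjusted over the list alone (camera adjusted p = 0.373), and the list's median log2 change was 0.23 and its mean -0.14. Esrrg, an orphan nuclear receptor tied to β-cell metabolism, rose by 2.04 on the log2 scale (SE 0.44, adjusted p = 0.0287). With old library 1, 2 or 3 left out, no factor was called higher and 1, 2 and 1 were called lower, and without the deeper young library 9 rose and 9 fell. Sox4 and Sox9, factors of pancreatic progenitors, fell with log2 changes of -3.21 and -5.58 and adjusted p of 0.00714 and 0.0438. Sox9 also stands in the list of duct cell markers, which fell with a median of -2.17, so its loss within β cells is not shown. Pdx1 had a log2 change of 0.88 (SE 0.28, adjusted p = 0.0757) and Nkx6-1 one of -0.16 (SE 0.36, adjusted p = 0.801). Mafa had 99 counts over the old and 31 over the young libraries, and a log2 change of -0.30 (SE 1.18, adjusted p = 0.894).

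Genes of the unfolded protein response rose more often than they fell in old cells. Of 30 tested, 10 rose and none fell, with 14 and none adjusted over the list alone, and the median log2 change was 0.99 (camera adjusted p = 6.46e-08, and adjusted p = 0.2 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum on chromosome 2 (34627610 to 34632049), rose from 716 ± 271 to 1867 ± 318 CPM, a log2 change of 1.38 (SE 0.30, adjusted p = 0.0294). Sel1l and Edem1, which act in the disposal of misfolded proteins, rose by 1.47 and 1.35, and Manf, a secreted stress-induced factor, by 1.70. Without old library 1 or 2 none of the 30 was called, and without old library 3 1 rose and 1 fell.

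Of 76 oxidative phosphorylation genes, 6 rose and none fell (4 adjusted over the list alone), and 68 had a positive fold change. Their median log2 change was 0.58 (camera adjusted p = 1.19e-06, and adjusted p = 0.124 with an estimated correlation). Sdha of complex II rose from 67.9 ± 3.18 to 259 ± 26.5 CPM, a log2 change of 1.93 (SE 0.24, adjusted p = 0.00547), and the complex I or IV genes Ndufa4, Ndufa9 and Cox7a2l rose by 1.56, 2.27 and 1.20. Leaving out any old library left 1 call. In glycolysis and the citrate cycle, 39 genes were tested, and the list passed camera with a median log2 change of 0.57 (adjusted p = 0.0254, and adjusted p = 0.144 with an estimated correlation), a call that was lost without old library 2 (adjusted p = 0.0544). Its median was 0.34 without the shallower young library. Aldoa, which encodes an enzyme of glycolysis, rose by 1.12 on the log2 scale, also when adjusted over the list alone, and was not called without any 1 old library. Transcripts of exocrine, endothelial and stromal cells were higher in the young libraries, as given further on, so that each rise above was measured beside a higher share of those transcripts in young libraries.

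Cell cycle genes were lower in old cells. Of 65 tested, none rose and 15 fell, or 29 adjusted over the list alone, with a median log2 change of -2.69 (camera adjusted p = 2.07e-10, and adjusted p = 0.0846 with an estimated correlation). Besides Mki67, Top2a fell from 43.7 ± 33.0 to 1.66 ± 0.32 CPM (log2 change -4.72, SE 0.61, adjusted p = 0.0061), Cenpf fell by 5.00 on the log2 scale, and the transcriptional repressor E2f8 was at least 430-fold lower with no count in old libraries. Among 26 G1 cyclins, growth factor receptors and imprinted growth genes, 10 fell and none rose (16 fell and 1 rose adjusted over the list alone), with a median of -2.44 (camera adjusted p = 3.64e-06, and adjusted p = 0.124 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell from 190 ± 23.9 to 35.3 ± 1.02 CPM (log2 change -2.42, SE 0.24, adjusted p = 0.00384), and Igf2bp2, Fgfr1 and Pdgfrb fell with log2 changes of -6.70, -4.01 and -3.92. Ccnd2, which encodes cyclin D2, had a log2 change of 0.75 (SE 0.21, adjusted p = 0.0572). Leaving out old library 1, 2 or 3 left 5, 7 or 5 called cell cycle genes and 4 of the G1 list each time, without the deeper young library the G1 median was -1.54 and 3 of its genes rose, and markers of exocrine, endothelial and stromal cells were lower in the same libraries.

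Of 23 cell cycle inhibitors and senescence genes, 6 fell and 1 rose (7 and 2 adjusted over the list alone), and the list's median log2 change was -0.57 (camera adjusted p = 0.0417, and adjusted p = 0.183 with an estimated correlation). The list's call was lost without old library 2 or 3 or the deeper young library (adjusted p = 0.0515, 0.0574 and 0.294) and with no filter (adjusted p = 0.103), and none of its genes was called without any 1 old library. The 4 falls with the smallest adjusted p were Igfbp7, Igfbp4 and Igfbp3, which encode secreted binding proteins of insulin-like growth factors, and Cd9, a tetraspanin, with log2 changes of -1.61, -4.76, -1.72 and -5.75. None of these blocks the cell cycle itself. Cdkn1a, which encodes the inhibitor p21, had a log2 change of -0.13 (SE 0.41, adjusted p = 0.865). Cdkn2a, the locus of p16 and p19, had 11 counts over the old and 2 over the young libraries and was not tested. Ezh2, the methyltransferase of Polycomb repressive complex 2, had a log2 change of -0.52 (SE 0.73, adjusted p = 0.677).

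Transcripts of other islet and pancreatic cell types were lower in old libraries in every such list that passed the test. Of 32 acinar genes, 22 fell and all had a negative fold change (26 called adjusted over the list alone, median -3.88, camera adjusted p = 2.02e-32). The chymotrypsinogen gene Ctrb1 fell from 1183 ± 334 to 68.1 ± 15.9 CPM (log2 change -4.12, SE 0.30, adjusted p = 0.00304). Of 22 stellate and fibroblast genes 20 fell (22 adjusted over the list alone, median -6.88, camera adjusted p = 1.87e-21), and the collagen gene Col1a2 fell from 451 ± 551 to 1.10 ± 0.538 CPM. Of 22 endothelial genes 16 fell (18 adjusted over the list alone, median -3.57, camera adjusted p = 5.44e-16), with Vwf, the von Willebrand factor gene, at -7.71 and Cdh5 at -3.47. Of 17 duct genes 9 fell (12 fell and 2 rose adjusted over the list alone, median -2.17, camera adjusted p = 4.78e-09), among them Krt19 with -8.24 and Spp1 with -3.91. With an estimated correlation the adjusted p of these 4 lists were 0.0846, 0.172, 0.144 and 0.0846. Without the deeper young library the stellate median was -4.24, with 16 of 21 called. Without 1 old library the calls fell to 14 to 17 acinar, 9 to 16 stellate, 7 to 9 endothelial and 4 to 7 duct genes.

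Among islet hormones, Sst of δ cells fell from 3497 ± 2750 to 94.3 ± 63.4 CPM (log2 change -5.21, SE 0.68, adjusted p = 0.00657) and Ppy of PP cells from 1227 ± 502 to 104 ± 54.7 CPM (log2 change -3.56, SE 0.47, adjusted p = 0.00672). Gcg, the glucagon gene of α cells, fell by 3.71 on the log2 scale (SE 0.94, adjusted p = 0.0432), and its level differed between the young libraries, at 1673 CPM in the shallower and 30470 CPM in the deeper one. Of 11 δ and PP genes 8 fell (11 adjusted over the list alone, median -3.65, camera adjusted p = 4.78e-09, and adjusted p = 0.0882 with an estimated correlation). Of 14 α-cell genes 3 fell (9 adjusted over the list alone, median -1.89, camera adjusted p = 0.0045, and adjusted p = 0.213 with an estimated correlation). The α-cell call was lost without the deeper young library (median -0.44, adjusted p = 0.242). Without old library 1, 2 or 3 the calls fell to 3, 4 and 2 δ and PP genes and to 0 α-cell genes each time. Of 26 macrophage and lymphocyte genes 5 fell, among them Cd74 and Mrc1 (10 adjusted over the list alone, median -2.70, camera adjusted p = 7.82e-06, and adjusted p = 0.0846 with an estimated correlation), and none was called without any 1 old library.

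Genes of immature β cells and genes normally kept low in β cells were lower in old cells. Of 25 tested, 12 fell and none rose (18 adjusted over the list alone), with a median log2 change of -3.95 (camera adjusted p = 1.1e-10, and adjusted p = 0.0882 with an estimated correlation). Hk1, the low-Km hexokinase that mature β cells keep low, fell from 24.5 ± 17.2 to 0.365 ± 0.345 CPM (log2 change -6.08, SE 0.97, adjusted p = 0.0118). Npy, a neuropeptide gene of fetal and neonatal islets, Zfp36l1 and Tgm2 fell with log2 changes of -5.16, -4.75 and -6.2. Of the listed genes, 7 also stand in another list, and 9 reached 1 CPM in every old library. Pdgfra, a receptor of growth signals in young β cells and of stromal cells, had 1 count over the old libraries against 480 over the young ones and fell (adjusted p = 0.0151). Without old library 1, 2 or 3 the list had 4, 6 and 4 called members, and without the deeper young library its median was -2.53. Markers of stellate, acinar, δ and PP and endothelial cells fell in the same libraries with medians of -6.88, -3.88, -3.65 and -3.57, so a loss within β cells is not shown.

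**Figure D2:**
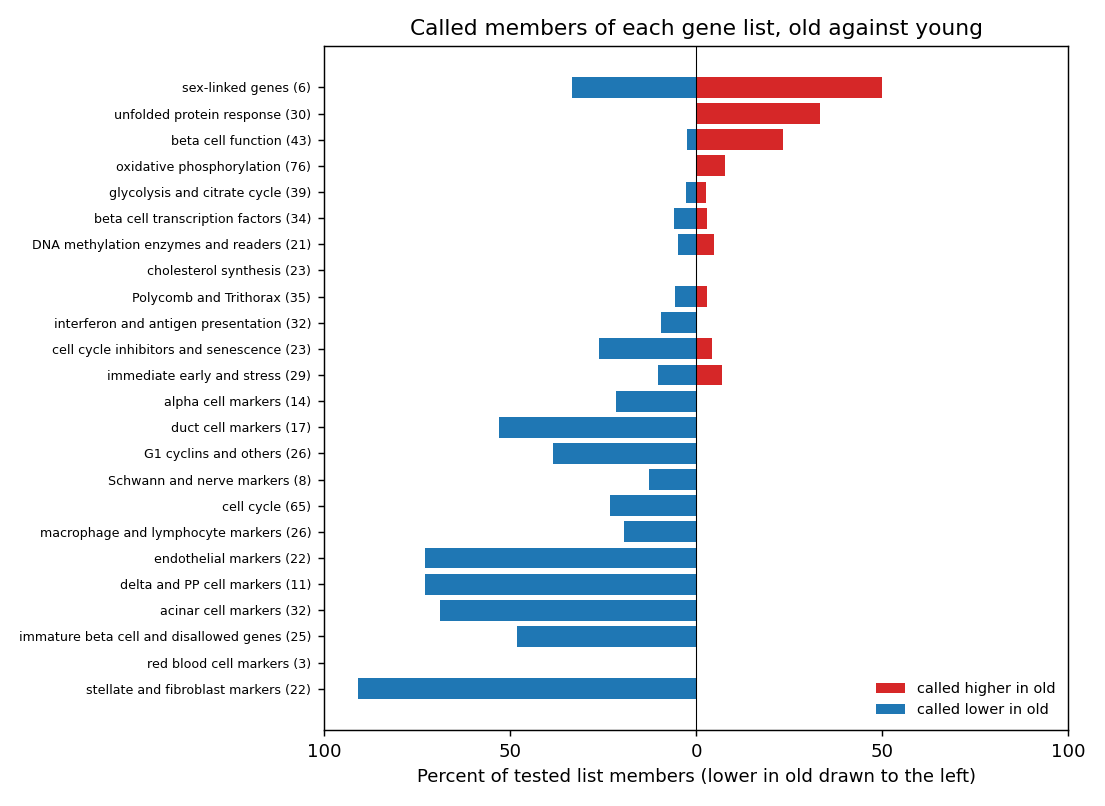
Percent of the tested members of each of 24 gene lists that were called higher (red, to the right) or lower (blue, to the left) in old than in young libraries, with the number tested in parentheses. Of the stellate and fibroblast list 20 of 22 members were called lower, and of the unfolded protein response list 10 of 30 were called higher.

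In the list of DNA methylation enzymes and readers, 1 of 21 genes rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.59). Uhrf1, which guides maintenance methylation in dividing cells, fell by 6.84 on the log2 scale (SE 1.37, adjusted p = 0.0235), and Apobec1 rose by 1.30 (adjusted p = 0.0292). Dnmt1 had a log2 change of 0.02 (SE 0.55), Dnmt3a one of 0.17 (SE 0.28) and Tet2 one of -0.34 (SE 0.23), none past the test (adjusted p = 0.991, 0.74 and 0.361), and the sign of Dnmt1 turned with RLE factors. Of 35 Polycomb and Trithorax genes, Bmi1 rose by 1.40 while Phf19 and Wbp7 fell with log2 changes of -5.29 and -1.12, with no call adjusted over the list alone (camera adjusted p = 0.648). Of 32 interferon and antigen presentation genes Ifih1, Bst2 and Oasl2 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.648). None of 23 cholesterol synthesis genes was called (camera adjusted p = 0.361), nor any called adjusted over the list alone. Without any 1 old library no methylation, Polycomb or Trithorax gene was called, and 0, 0 and 1 interferon gene.

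Of 29 immediate early and stress genes, Mt1 and Mt2, which encode metallothioneins, rose by 1.05 and 1.68, while Fosl2 and Klf4 fell with log2 changes of -2.25 and -3.37. In total 2 rose and 3 fell (2 and 5 adjusted over the list alone, median -1.23, camera adjusted p = 0.00369, and adjusted p = 0.507 with an estimated correlation). The list's call was lost without the deeper young library (adjusted p = 0.273). Its calls followed the old libraries too: without library 1, 2 or 3, 0, 1 and 11 genes fell and none rose, and without the third the median was -2.08 (camera adjusted p = 2.52e-12). Of 8 Schwann and nerve genes only Erbb3 fell (5 adjusted over the list alone, camera adjusted p = 0.041, and adjusted p = 0.183 with an estimated correlation), with the list's call lost without old library 1 or 2 or the deeper young library (adjusted p = 0.0656, 0.0594 and 0.436), and none of 3 red blood cell genes was called (2 adjusted over the list alone, camera adjusted p = 0.19). Xist, the RNA that coats the inactive X chromosome, fell from 446 ± 203 to 2.90 ± 0.278 CPM (log2 change -7.26, SE 0.37, adjusted p = 0.000313), while the Y-linked Eif2s3y and Uty rose by 2.56 and 1.70. Without old library 1, 2 or 3, 0, 0 and 1 sex-linked genes were called higher, and 2 lower each time. The labels do not give the sex of the pooled animals. Of 535 X-linked genes 11.2% were called, beside 11.1% of 14959 autosomal genes, but the directions differed. On the X chromosome 31 rose and 29 fell, and the median log2 change of its tested genes was 0.245. On autosomes 458 rose and 1203 fell, and the median was -0.059.

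Averaged over CpGs, methylation hardly differed between the old and the young bisulfite library. Over 15451578 CpGs the mean level was 74.4% in young and 74.2% in old cells, and 18 of 19 autosomes were lower in old by this measure. The difference of -0.15 points was -0.41 at a minimum of 1 call and 0.06, reversed, at a minimum of 10 calls. Weighted by coverage, the level was 75.33% in young (95% exact interval 75.329 to 75.335) and 71.81% in old (71.805 to 71.812), a difference of -3.52 points. That weighted value followed the most deeply covered CpGs, those above 148 young or 110 old calls. Without them, 15422025 CpGs and 361496070 of 796524984 young calls were left, and the weighted difference was 3.16 points in the opposite direction. The deepest, 1 CpG on chromosome 2 at 98507306, held 57348820 young and 20596265 old calls, and its own effect was not tested. With 1 library per age the difference between the ages has no replicate check.

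At H3K4me1 and H3K27ac peaks, losses of methylation in the old library outnumbered gains, which they did not do in 1 kb windows over the genome. Of 26185 young H3K4me1 peaks tested, 2538 were lower and 1084 higher in old by at least 20 points, so that 70.1% of calls were losses (95% exact interval 68.6 to 71.6). Old H3K4me1 peaks gave 1111 losses and 494 gains of 12082 tested (69.2% losses), and young H3K27ac regions 694 losses and 127 gains of 14652 (84.5% losses). In contrast, 1 kb windows over the genome gave 54649 losses and 57504 gains of 1666447 (48.7% losses), and young H3K27me3 regions 131 losses and 154 gains of 31050 (46.0% losses). The 1 kb windows had a higher median level in young cells (84.9%) than young H3K4me1 peaks (18.0%). Windows matched to these peaks on width, level and number of CpGs gave 56.5% losses. The median difference per region was small, at -0.98 points over young H3K4me1 peaks and -1.2 points over H3K27ac regions, and pooled over calls the young H3K4me1 peaks were at 17.88% in young and 18.09% in old cells. Centring on the weighted genome-wide difference, which the deepest CpGs set, lowered the share of losses to 56.3% in young H3K4me1 peaks, 67.7% in H3K27ac regions and 30.7% in windows. Most H3K4me1 peaks held too few CpGs for a test, since 26185 of 77291 young and 12082 of 36207 old peaks qualified.

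**Figure D3:**
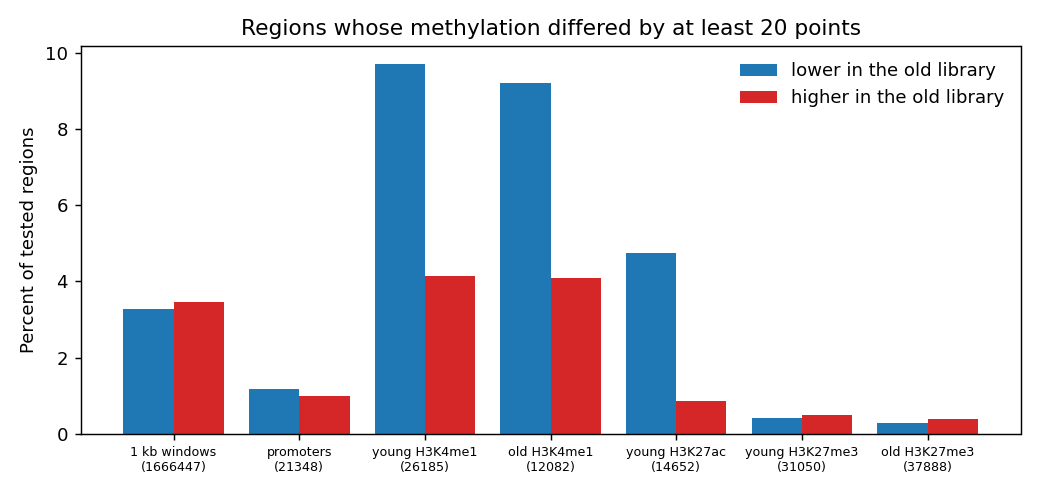
Percent of tested regions of each kind whose methylation was lower (blue) or higher (red) in the old than in the young bisulfite library by at least 20 points at an adjusted p under 0.05 (Fisher's exact test), with the number of regions tested in parentheses. Losses exceed gains in H3K4me1 and H3K27ac peaks, with 9.69% against 4.14% in young H3K4me1 peaks, and not in 1 kb windows. These windows were not matched to the peaks in methylation level.

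The largest loss in young H3K4me1 peaks lay on chromosome 8 at 71601245 to 71601371, within the span of Slc18a1, a vesicular monoamine transporter gene, where 38 of 38 young calls and 0 of 38 old calls over 5 CpGs were methylated (adjusted p = 1.01e-19). Others lay within Csgalnact1 (90.4% to 4.3%), at -39448 bp from the start of Tox2 (84.8% to 4.0%) and within Arfgap2 (86.8% to 11.1%). The largest gains lay within Cdhr3 (7.7% to 66.7%) and at 225566 bp past the start of Etaa1 (1.3% to 57.9%). Among old H3K4me1 peaks the losses included a site within Lrig1 (90.9% to 7.7%), a site within Rbpj, the transcriptional effector of Notch (73.1% to 7.3%), and one within Myc, the growth regulator, 2079 bp past its start on chromosome 15 at 61818915 to 61819035 (78.2% to 12.6%, 142 young and 103 old calls, adjusted p = 7.25e-23). The largest gain of that list lay 2 bp past the start of Scn9a, a sodium channel gene (3.1% to 52.6%).

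Near genes of cyclins and β-cell factors, called peaks went both ways. Both peaks named for Ccnd2, at -3052 and -2532 bp from its start on chromosome 6, were lower in old (42.4% to 10.6% and 55.3% to 29.4%), and the peak named for Ccnd1 was lower too (56.4% to 34.9%). A peak at -10266 bp from Mafa fell from 37.0% to 13.9%. Nkx6-1 had a peak at -23940 bp that was lower (64.3% to 40.2%) and one at -36529 bp that was higher (0% to 33.3%, 33 young and 21 old calls). Peaks near the hormone genes of other islet cells were lower in old: 86.2% to 29.6% at 3363 bp past the start of Ppy and 69.4% to 43.2% at 26891 bp past the start of Gcg. A peak 1057 bp past the start of Dnmt1 was higher (11.5% to 37.9%).

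Few promoters were called, with 252 losses and 210 gains among 21348 tested. The promoter of Ins1 on chromosome 19 fell from 54.8% to 9.7% methylation (6 CpGs, 73 young and 186 old calls, adjusted p = 8.19e-13), and that of Gpr119, a lipid receptor of β cells, from 28.4% to 5.5%. The bisulfite samples are labelled C57Bl6 without the reporter. If their mice carried it, reads of its insulin promoter can fall on an insulin gene, which was not measured. A larger share of other cell types in the young bisulfite pool stays open too, as given further on. A loss of methylation within β cells is therefore not shown. The promoter of Igfbp5 fell from 37.3% to 5.1%. The promoters of Pyy, Epcam and Arhgdib, genes of PP, duct and immature or disallowed lists, rose from 47.8% to 71.9%, from 34.9% to 58.4% and from 48.4% to 72.7%. No promoter of the 65 cell cycle, 76 oxidative phosphorylation or 30 unfolded protein response genes was called. In the remaining lists Spink3 of acinar cells and the Y-linked Uty differed by -23.7 and -20.5 points. Promoters other than that of Ins1 were chosen for naming after their values were seen.

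Fewer H3K4me1 peaks and more H3K27me3 regions were listed for old cells. The lists held 77291 young and 36207 old H3K4me1 peaks, from 27179660 and 23133696 tags with 12.45% and 6.00% of tags in peaks per the file headers, so that a peak missing from the old list is not shown to be lost. Of young H3K4me1 peaks 16.7% overlapped an old peak, and of old peaks 35.6% overlapped a young one. H3K27me3 regions covered 451.82 Mb in young and 649.15 Mb in old cells, where it is open whether the old list joins 2 replicas, and 70.5% of young regions overlapped an old one, beside 49.8% of old regions overlapping a young one. The X chromosome held 1.26% of young and 0.54% of old H3K4me1 peaks, and 5.44% of young and 9.49% of old H3K27me3 regions. H3K4me1 peaks of both ages, of young only and of old only had median methylation differences of -0.77, -1.06 and -0.95 points, and neither young only (permutation p = 0.11, adjusted 0.275) nor old only (permutation p = 0.337, adjusted 0.562) passed a test against those of both ages. Old-only H3K27me3 regions lay 0.34 points above those of both ages (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 5e-05), and young-only regions -0.04 points from them (permutation p = 0.532, adjusted 0.573).

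Genes marked by H3K27me3 at their start in both ages were lower in old cells. The median log2 change of these 2723 genes was -2.84, beside 0.22 in 9191 genes marked in neither age (difference -3.06, permutation p = 1e-05, the smallest possible, adjusted 1.33e-05), and 25.3% of them fell, beside 2.8%. Without old library 1, 2 or 3 that share was 7.8%, 11% and 6.4%, beside 0.5% to 0.7%, and the difference of medians -3.07 to -3.14. Without the deeper or the shallower young library it was 30.8% beside 8.8% and 32.0% beside 5.2%, with differences of -2.43 and -2.68. The lists differed in this mark: 84% of immature or disallowed genes, 90.9% of δ and PP genes and 77.3% of stellate genes carried it in both ages, beside 9.2% of cell cycle, 6.7% of unfolded protein response and 2.3% of β-cell function genes. Markers of δ and PP, stellate, endothelial and α cells, with the mark in 50% of the endothelial and of the α-cell list, fell in the same libraries with medians of -3.65, -6.88, -3.57 and -1.89, so the lower level of marked genes is not shown to lie within β cells. Mki67, Gcg, Sst, Ppy, Pyy and Col1a1 (the last chosen after its value was seen) were marked in both ages, whereas Ctrb1 and Ezh2 were marked in neither. Genes marked only in old cells (2982) had a median of -0.32, or -0.53 against those marked in neither (permutation p = 1e-05), and 602 genes marked only in young cells had a median of 0.14, or -0.08 (permutation p = 0.11). Genes marked only in young cells lay 0.45 above those marked only in old cells (permutation p = 1e-05), or 0.26 without the deeper and 0.65 without the shallower young library. The young-only difference was 0.13 without the shallower and -0.20 without the deeper young library, so its direction rested on the young libraries.

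Genes next to H3K4me1 peaks that lost methylation showed no difference past the test from genes next to tested peaks that were not called. The 412 genes near losses had a median log2 change of -0.13, beside -0.19 in 4067 genes (difference 0.06, permutation p = 0.403, adjusted 0.543), and 203 genes near gains differed by 0.06 (permutation p = 0.543). Near young H3K27ac regions that lost methylation, 318 genes lay 0.24 above the 8557 others (permutation p = 0.00066, adjusted 0.00132), and 18 of them (5.7%) rose, beside 3.1% (Fisher's exact p = 0.0139). However, 68 genes near H3K27ac regions that gained methylation also lay above, by 0.31 (permutation p = 0.0354), and loss was not tested against gain. Genes whose promoter gained methylation were lower in old cells: 67 of them differed from those with promoters not called by -2.18 (permutation p = 1e-05, adjusted 2e-05), though 13.4% of them fell, beside 7.9% (Fisher's exact p = 0.107). That difference was -1.17 without the deeper and -1.36 without the shallower young library, and -1.10 at a minimum of 10 calls. Markers of other cell types fell in the same libraries, with medians of -6.88 (stellate), -3.88 (acinar) and -3.65 (δ and PP). The lower level of genes with such promoters is therefore not shown to lie within β cells. The 96 genes whose promoter lost methylation differed by -0.13 (permutation p = 0.376). The latter value was 0.57 without the shallower (permutation p = 0.0015) and -0.42 without the deeper young library (permutation p = 0.0215), so its direction rested on the young libraries.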

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

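Mitochondrial CpGs lay outside the comparisons above. There, 6.33% of calls in the young and 4.51% in the old bisulfite library were methylated, over 219 CpGs. Whether these calls came from incomplete conversion was not tested. All tests on cell cycle genes and those of other cell types on Y-linked genes, Xist and H3K4me1 losses were chosen after the result was seen. The tests of matched windows, of coverage and of escape genes were set before their values were seen, though the patterns they address were known by then.

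Cell cycle transcripts were lower in the old libraries. The log2 ratio of the deeper to the shallower young library had a median of 0.37 for the cell cycle list and 3.12 for 22 stellate genes, a difference of -2.75 (permutation p = 1e-05, the smallest possible), which argues against RNA of stellate cells, whose most abundant gene Sparc lay at 734 CPM in young and 15.8 CPM in old libraries. With old libraries thinned to the depth of the shallowest library, 22 members were called lower, which argues against lower depth of the young libraries. RNA of acinar, duct or endothelial cells stays open, since the ratio of 0 of these 3 lists departed from that of the cell cycle list by the bounds set (0.51, -0.11 and 1.26), and their top genes Ctrb1, Clu and Eng were higher in young libraries, with 20 of 32, 12 of 17 and 15 of 22 members also at 1 CPM or more in every old library. RNA of macrophages and lymphocytes stays open as well, since their list had a ratio of 0.52 (permutation p = 0.864 against the cell cycle list). The sort for the insulin reporter is meant to remove other cell types. Transcripts of acinar, duct and endothelial cells were still found in both groups, so the sort does not exclude this source. Fewer dividing β cells with age remains an open, untested explanation.

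Xist was lower and 3 of 4 tested Y-linked genes were called higher in old libraries. The median log2 change of the Y-linked genes was 1.64, beside 0.61 for genes of β-cell function, a difference of 1.03 (permutation p = 0.0107), which argues against dilution of Y-linked transcripts by RNA of other cell types in the young libraries, since dilution would raise β-cell genes at least as much. Xist RNA of other cell types stays open: between the young libraries the log2 ratio of Xist was 0.97, and only 2 of 7 lists of other cell types departed from it by more than 1. Such RNA would itself need females in the young pools. A different sex makeup of the pools stays open too. Fewer females in the old pools would give both lower Xist and higher Y-linked transcripts. The genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x, which escape X inactivation and would be lower in old libraries with fewer females, differed from the other X-linked genes by 0.01 (permutation p = 0.993), too few genes to decide. Young libraries held Y-linked transcripts too. Sex, if it differed, could not be told apart from age in any RNA result here, and age itself as the reason was not tested.

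More H3K4me1 peaks had lower than higher methylation in the old library. Windows of the same width outside H3K4me1 peaks, matched on methylation level and number of CpGs, had 56.5% losses among calls beside 70.1% in the peaks, which argues against a genome-wide difference as the whole cause, though part of the excess is shared with such windows. Among peaks with a ratio of old to young calls close to the median the share was 69.4% (95% exact interval 66.7 to 72.0, 1213 called peaks), which argues against coverage. A larger share of other cell types in the young bisulfite pool stays open: 115 promoters of other cell type markers at 10% to 90% methylation had a median difference of 0.89 points, beside -0.1 in other promoters (permutation p = 0.247), while 27 promoters of β-cell genes had -5.9 (permutation p = 0.0016). A change within β cells with age is likewise open, and with 1 library per age an animal or pool effect cannot be excluded.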

How the results depend on the processing

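The settings chosen after seeing the data are named with the processing. Of the 1724 called genes, RLE factors kept 1608, no filter 1606 (of 2492 called, 823 higher) and the filter at 5 CPM 1132 (of 1188), and each shifted the count by less than 1.5 times. DESeq2 called 4154 genes and included all 1724. Leaving out 1 library gave 331 (without old library 1) to 5467 genes (without the deeper young library), where a single young library is assumed to vary like the old ones. Why the loss of an old library lowered the count was not tested. All transcripts, counts summed over transcripts, library sizes without Ins1 and Ins2, and thinned old libraries gave 2465, 1528, 1725 and 1842. Of the 24 lists, 17 passed camera, 13 to 18 with a library left out, 14 with fry and 0 with an estimated correlation, while 4644 genes had an unadjusted p under 0.05. Among named genes, gene Dnmt1 turned to -0.08 with RLE factors, -0.10 with the filter at 5 CPM, -0.08 with DESeq2 and -0.02 without Ins1 and Ins2 in the library size, and ranged from -0.67 to 1.43 with a library left out. With a library left out, gene Nkx6-1 ranged from -0.62 to 0.53, gene Cdkn1a from -0.47 to 0.33 and gene Dnmt3a from -0.19 to 0.66, and the cause was not tested.

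The weighted genome-wide methylation difference was -3.23 points at a minimum of 1 call, -4.14 at 10 calls, -3.38 on autosomes, -0.15 as an unweighted mean of CpGs (-0.41 at 1 call and 0.06 at 10 calls) and 3.16, reversed, without the most deeply covered CpGs, which shows that the deepest CpGs set its sign. Called regions follow the required difference. At 10 points, 7004 young and 3225 old H3K4me1 peaks, 2601 H3K27ac, 2024 young and 1972 old H3K27me3 regions, 287016 windows and 1959 promoters were called, with 63.8%, 61.8%, 80.5%, 52.3% and 48.8% losses in the peak lists and 49.8% in windows. At 30 points, the counts were 1538, 673, 236, 59, 53, 35123 and 109, with 76.8% and 76.2% losses in young and old H3K4me1 peaks and 46.3% in windows. Centring gave 56.3% losses in young and 54.9% in old H3K4me1 peaks, 67.7% in H3K27ac regions, 23.3% in young and 19.6% in old H3K27me3 regions, 30.7% in windows and 31.3% in promoters. In the upper 50% of each list by score, 2040, 883, 308, 25 and 78 regions were called, with 88% losses in H3K27ac and 36% in young H3K27me3 regions. H3K4me1 peaks widened to 500 bp on each side of their centre gave 6783 young and 3043 old calls with 79.4% and 80.3% losses. On autosomes 167 young and 79 old H3K27me3 regions were called, and with 1 CpG per 100 bp the young H3K27me3 regions had 52.5% losses. At a minimum of 10 calls 73292 windows were called with 47.8% losses, and at 3 calls 49.3% were losses. Losses stayed the larger share in both H3K4me1 lists and in H3K27ac regions in each setting that gave a value.

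Of the 4 differences between peak classes that passed no test, those of young-only and old-only H3K4me1 peaks kept their sign and the others turned: shared H3K4me1 peaks with against without H3K27ac gave -0.30 points at an overlap of 50%, and young-only against shared H3K27me3 regions 0.10 at 10 calls and 0.01 at 3 calls. With an overlap of 50%, higher-scoring peaks and lists of equal length, 10.8%, 15.9% and 25.03% of young H3K4me1 peaks overlapped an old one, and 23.8%, 33.8% and 25.03% of old peaks a young one. For H3K27me3 regions the values were 60.2%, 65.7% and 64.9% of young and 34.3%, 46.9% and 53.8% of old regions. For genes near losses the difference was 0.24 with H3K27ac regions, -0.10 at 30 points and -0.08 to 0.14 with a library left out, and near gains 0.31 with H3K27ac regions and -0.02 at 10 points. Genes marked by H3K27me3 only in young cells differed by -0.29 with higher-scoring regions and by -0.20 to 0.13 with a library left out. Genes with a promoter that lost methylation differed by 0.03 at 10 calls, 0.04 at 3 calls, -0.24 at 10 points (permutation p = 7e-05), 0.02 at 30 points and -0.42 to 0.57 with a library left out, and the cause was not tested. For promoters that gained methylation the difference was -1.10 at 10 calls, -1.38 at 3 calls, -1.09 at 10 points and -1.17 to -2.17 with a library left out. No paired analysis was possible because the young RNA columns carry no replicate number, so the planned replicate block was not run. The 2 planned fits on the FPKM table were not run because 2 of its columns are identical, and 1 CpG per 100 bp left no H3K4me1 peak to test.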

Other observations

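The sex-linked signals of the 3 kinds of data did not line up, and no explanation of this was tested. In the RNA, Xist lay at 446 CPM in young and 2.90 CPM in old libraries. In the bisulfite libraries, CpGs of the X chromosome held 0.471 of the calls of an autosomal CpG in young and 0.425 in old cells. CpGs of the Y chromosome averaged 14.14 young and 13.49 old calls, close to the 14.35 and 13.5 of the X chromosome. Such depths argue against a large share of females in either bisulfite pool. Whether the RNA and bisulfite pools held the same animals was left open. The share of H3K27me3 regions on the X chromosome was 5.44% in young and 9.49% in old cells, while Xist, the RNA that brings this mark to the inactive X, was low in the old RNA libraries.

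The young libraries differed from each other more in some cell types than in others. Alpha cell genes were higher in the deeper than in the shallower young library by a median of 1.83 on the log2 scale (14 genes), δ and PP genes by 1.54 (11 genes) and macrophage genes by 0.52 (26 genes). The shallower young library, with 6377619 counts, detected 18821 genes, beside 16702 in the deeper one and 15850 to 16912 in the old libraries.

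Transcripts of Prlr, the prolactin receptor that sits among the growth factor receptors, averaged 1400 CPM in young and 1890 CPM in old libraries, and Igfbp5 averaged 256 and 524 CPM, chosen here after their values were seen as the most abundant members of their lists. The Igfbp5 promoter was 37.3% methylated in young and 5.1% in old cells over 32 CpGs (483 and 490 calls). One CpG on chromosome 9 at 35113019, the deepest of that chromosome, held 8095033 young and 2928791 old calls. Other CpGs of such depth were not counted.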
